A study of Mus musculus with 16 samples.

How the data were processed

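Messenger RNA was measured in 16 libraries of antigen-specific donor B cells sorted from pooled spleens on day 10 after immunisation: 3 of the light zone gate (LZ), 2 of Fraction 2, 3 of Fraction 3, 3 of Fraction 5, 2 of Fraction 6 and 3 of Fraction 7. Per the labels' protocols, RNA was isolated with TRIzol, libraries were made with a NEBNext Ultra RNA kit, which does not mark the strand, and sequenced on an Illumina HiSeq, so reads of overlapping antisense genes are not separated. Per the submitters' processing notes, the authors aligned reads with TopHat2 2.0.8 to mm9 and made the deposited FPKM values with Cufflinks 2.1.1. The deposited table holds FPKM for 23234 genes with a name, and 1 row without a gene name was left out. The gene table at hand is of another build, GRCm38.p6, and was used only to match symbols, so no coordinates are given. Listed genes found under an older symbol were Gcsam (Gcet2), Nuggc (Gm600), Pkm (Pkm2), Msmo1 (Sc4mol), Jchain (Igj), Mzb1 (2010001M09Rik), Ackr3 (Cxcr7), Adgre1 (Emr1) and Hbb-bs (Beta-s), and Hbb-bt, Ahsp, Ighd and Ighm were not found under any symbol. The list entry Cd23 is another name of Fcer2a, which was listed and found.

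Genes with at least 1 FPKM in at least 2 libraries were tested (11266 genes). Values were set to log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 fitted 1 model with the 6 groups as means over all 16 libraries, with a trend of variance on mean expression and equal weights. Comparisons were Fraction 2 against Fraction 3, Fraction 5 against Fraction 3 and against Fraction 2, Fraction 6 against Fraction 5, Fraction 7 against Fraction 6, and Fraction 7 against LZ. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. FPKM are not counts, so tools made for counts were not used. Comparisons that share libraries share their chance values, and no overlap of calls between them was tested.

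Gene lists were written before the files were opened: 22 lists of pathways and B cell states and 8 lists of markers of other cells. The 26 lists with at least 5 tested genes were tested with limma's camera at its preset correlation between genes of 0.01, and again with a correlation estimated from the data and with fry, a rotation test, each adjusted over the lists within a comparison. The lists cover ribosome biogenesis, mTORC1-associated genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, S phase, mitosis, proteasome, ribosomal proteins, BCR pathway, early activation, survival, apoptosis, antigen presentation, plasma cell, migration, interferon response, light zone, dark zone, GC identity, memory, and quiescence with egress. Counts of members that rose or fell use p-values adjusted over all genes, and beside them stand counts adjusted over the list alone. Some genes are members of more than 1 list.

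Genes named in the report were chosen by a rule written before the files were opened. In each comparison it takes the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the groups. It adds up to 4 members of each list past its threshold, by smallest adjusted p in the list's direction, the sort genes, a fixed panel, and up to 2 most abundant markers of each other cell type. From these the account was kept mostly to genes whose call held when any 1 library was left out, a choice made after those values were seen. Of 545 results that the rule gives past the threshold, 101 lost their call in at least 1 such fit.

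Relative depth was read from the smallest steps of low values in each library, which scale with 1 fragment. It lay between 0.921 and 1.21 times that of LZ library 1, and the true number of reads is unknown. The model was tested on simulated data, with 200 genes changed among 11266: at a log2 change of 1 it recovered 91% for Fraction 2 against Fraction 3, 93% and 91% for Fraction 5 against Fractions 3 and 2, 89% for Fraction 6 against Fraction 5, 88% for Fraction 7 against Fraction 6 and 92% for Fraction 7 against LZ, with 0 of wrong sign. Unchanged genes called numbered 13, 8, 10, 6, 8 and 11 in that order. Noise was normal, independent between genes and drawn from the model's own variance, and only genes well above the filter were changed. Real genes are correlated and far more of them were called, so these rates may be too favourable.

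Alternatives were quantile normalization, median-ratio scaling, a pseudocount of 0.1, no filter and a filter of at least 5 FPKM in 2 libraries, a fit to the groups compared alone, the replicate number as a block, array weights, each library left out in turn, and other references (LZ for Fraction 5, Fraction 3 for Fraction 7). Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Ighg1 is not analysed here, and some genes that the rule gives are not reported here.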

Results

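RNA sequencing compared gates of antigen-specific mouse B cells, from the light zone of the germinal centre (GC) to memory, all sorted on day 10. B1-8hi B cells, whose receptor binds the hapten NP, carried a Bcl6-YFP reporter and were transferred into CD45.1 mice, which were then immunised with the NP-carrying protein CGG in alum. On day 10, spleen cells of 9 recipients were pooled and NP-binding, IgG1-positive, CD138-negative donor cells were sorted into 6 gates. The LZ gate (n = 3) held CD38-negative, CD86-high, CXCR4-low light zone cells. Fraction 2 (n = 2) and Fraction 3 (n = 3) were Bcl6-YFP-high light zone cells with high or low CD69, which the labels call prone to recycling and under selection. Fraction 5 (n = 3, called pro-memory), Fraction 6 (n = 2, pre-memory) and Fraction 7 (n = 3, mature memory) were CD38-positive and GL7-negative. Fraction 5 was high for Bcl6-YFP and for the surface ligand Efnb1, Fraction 6 low for Bcl6-YFP and high for Efnb1, and Fraction 7 low for both.

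The deposited values are FPKM, which summed to between 416741 and 492578 in the 16 libraries, with 10133 to 10552 genes at 1 FPKM or more in each. Relative depth, read from the smallest steps of low values, lay between 0.921 and 1.21 times that of LZ library 1 and the absolute number of reads is unknown. Values below are mean FPKM ± SD over the libraries of a group. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes, and a number alone in brackets after a gene is such a change. Adjusted p-values are from limma or, for gene lists, from its camera test. Where a fit leaves a group with 1 library, that library is assumed to vary like the other groups. The labels do not say whether the libraries of a group came from separate pools of mice, so p-values measure only the spread between these libraries, which may be technical.

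Transcripts of the genes behind the gates served as a check of the labels and are no findings. They were not taken out of the gene lists, where the sort itself may have set part of the change. Bcl6 and Efnb1 are in the GC identity list, Cd86 in light zone and antigen presentation, and Cxcr4 in dark zone and migration. Cd69 is in the early activation list, Sdc1 in plasma cell and Ptprc in BCR pathway. Bcl6 lay between 145.1 and 205 FPKM in the libraries of LZ and Fractions 2, 3 and 5, at 75.3 and 70.2 in Fraction 6 and between 15.01 and 20.5 in Fraction 7. Efnb1 was 57.9 to 67.5 FPKM in Fraction 5, 32.4 and 27.5 in Fraction 6 and 1.93 to 2.37 in Fraction 7. Cd38 was 8.92 to 12.8 FPKM in LZ and Fractions 2 and 3, 48.2 to 49.2 in Fraction 5 and 71.3 to 77.0 in Fractions 6 and 7. Cd69, the marker that parted Fraction 2 from Fraction 3, stood at 13.4 and 13.3 FPKM in the Fraction 2 libraries. It was at 11.5, 9.49 and 14.4 in the Fraction 3 libraries, and this difference did not pass the test (adjusted p = 0.361). The gates were set on CD69 protein and these values are mRNA, so they cannot decide whether the gates differed in CD69 protein. Sdc1, which encodes the plasma cell marker CD138 that the sort excluded, was at or below 0.534 FPKM in 14 libraries and at 4.44 and 4.51 in libraries 2 and 3 of Fraction 7. Cd86 ranged from 41.9 to 48.7 FPKM in Fraction 7 and from 69.5 to 123 in the other libraries, and Cxcr4 from 14.4 FPKM in a Fraction 7 library to 77.5 in a Fraction 5 library. Ptprc, which encodes CD45, ranged from 234 to 347 FPKM, and the switched constant region gene Ighg1 is not analysed here.

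**Figure D1:**
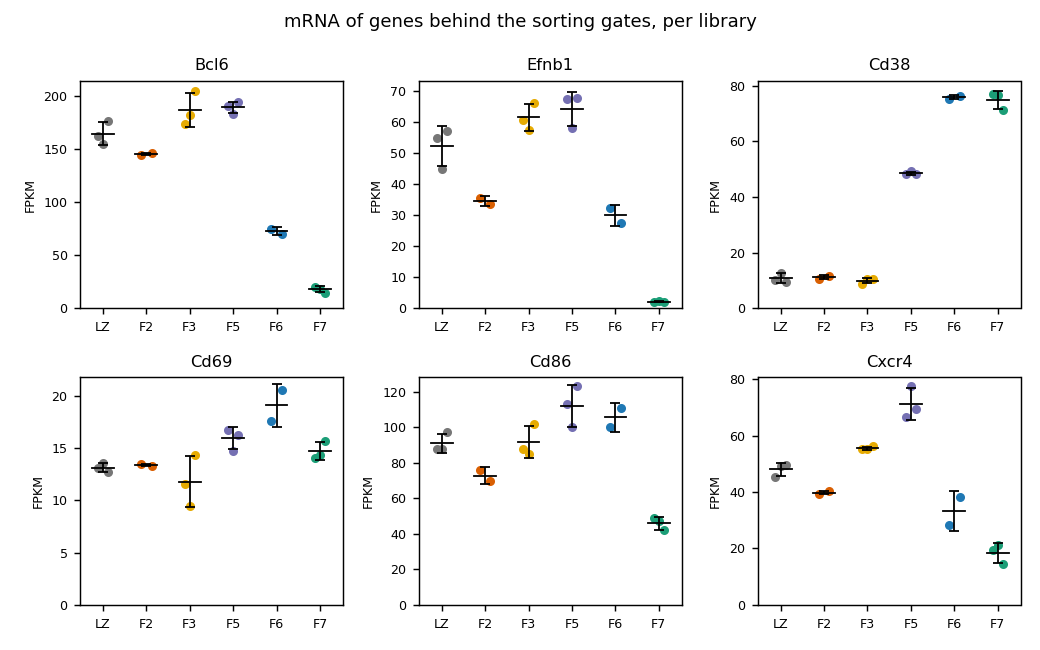
FPKM of 6 genes behind the gates in LZ and Fractions 2, 3, 5, 6 and 7 (F2 to F7), with 1 point per library, a bar at the group mean and whiskers of 1 SD. Bcl6 fell from a mean of 189 FPKM in Fraction 5 to 18 in Fraction 7, while mean Cd69 was 13.4 in Fraction 2 and 11.8 in Fraction 3.

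Fractions 2 and 3 share a Bcl6-YFP-high light zone gate and differ in CD69, so their comparison asks how cells called prone to recycling differ from cells under selection. Fraction 2 carried more mRNA of Myc, a transcription factor that drives cell growth (50.003 ± 6.56 against 24.4 ± 2.97 FPKM, log2 change 1.01 ± 0.13 SE, adjusted p = 0.000787). The cell cycle gene Ccnd2 rose (11.2 ± 0.344 against 2.12 ± 0.315 FPKM), as did the transcription factor gene Batf (52.2 ± 5.77 against 20.8 ± 1.44 FPKM). Irf4 (8.53 ± 0.529 against 4.03 ± 0.077 FPKM) and the amino acid transporter gene Slc7a5 (38.5 ± 4.48 against 20.8 ± 3.18 FPKM) rose as well. Among the largest rises were the TNF receptor family gene Tnfrsf8 (9.97 ± 1.19 against 1.35 ± 0.626 FPKM) and Shmt1 of serine and folate metabolism (30.4 ± 0.0501 against 11.3 ± 1.76 FPKM). Others were Gstt2 (1.52), Smyd2 (1.47) and Arid5a (1.42). The transcription factor gene Bach2 fell (27.3 ± 1.25 against 49.4 ± 4.19 FPKM). Pafah1b3 (-1.36), Ccrl1 (-1.23), Pik3cg (-1.19) and Acp5 (-1.11) were among the largest falls.

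Genes for making ribosomes moved most uniformly between these gates. Ribosome biogenesis genes rose as a list, with 26 up and 0 down of 30 (29 and 0 adjusted over the list alone; camera adjusted p = 4.01e-20, adjusted p = 0.209 with an estimated correlation). Gnl3 (1.24), Ncl (0.85) and Polr1b (1.07) were among the rises. Genes associated with mTORC1 rose as a list, with 19 up and 0 down of 32 (21 and 1 adjusted over the list alone; camera adjusted p = 6.24e-08, adjusted p = 0.303 with an estimated correlation). They included the chaperonin genes Hspd1 (1.02) and Cct6a (0.86). Glycolysis genes rose as a list, with 10 up and 2 down of 19 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00221, adjusted p = 0.407 with an estimated correlation), with Ldha (0.64) and Hk2 (0.81) among the rises. Survival genes rose as a list, with 6 up and 2 down of 16 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0178, adjusted p = 0.407 with an estimated correlation). The Bcl2a1 paralogs among these may share reads. Light zone genes rose as a list, with 9 up and 0 down of 22 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00137, adjusted p = 0.309 with an estimated correlation), Nfkbia (0.59) among them.

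Further lists went the same way. Proteasome subunit genes rose as a list, with 8 up and 0 down of 28 (13 and 0 adjusted over the list alone; camera adjusted p = 3.99e-06, adjusted p = 0.385 with an estimated correlation). Oxidative phosphorylation genes rose as a list, with 7 up and 0 down of 54 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00096, adjusted p = 0.45 with an estimated correlation). Mitosis genes rose as a list, with 4 up and 0 down of 34 (4 and 0 adjusted over the list alone; camera adjusted p = 1.83e-05, adjusted p = 0.45 with an estimated correlation). S phase genes rose as a list, with 1 up and 1 down of 38 (0 and 1 adjusted over the list alone; camera adjusted p = 0.00849, adjusted p = 0.492 with an estimated correlation). Cytosolic ribosomal protein genes rose as a list, with 5 up and 0 down of 55 (3 and 0 adjusted over the list alone; camera adjusted p = 0.00154, adjusted p = 0.578 with an estimated correlation). With fry, a rotation test, the last 3 lists did not pass, with an adjusted p of 0.066 for mitosis, 0.0897 for S phase and 0.108 for ribosomal proteins.

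Other lists were lower in Fraction 2. BCR pathway genes fell as a list, with 0 up and 17 down of 31 (1 and 23 adjusted over the list alone; camera adjusted p = 4.03e-13, adjusted p = 0.278 with an estimated correlation). The adaptor gene Dok3 (-0.86) and the receptor chain gene Cd79b (-0.62) fell. GC identity genes fell as a list, with 1 up and 9 down of 21 (2 and 10 adjusted over the list alone; camera adjusted p = 1.63e-06, adjusted p = 0.309 with an estimated correlation). Gm600 (-0.86) and Spib (-0.46) fell, the first now called Nuggc. Quiescence and egress genes fell as a list, with 0 up and 7 down of 22 (0 and 7 adjusted over the list alone; camera adjusted p = 0.000149, adjusted p = 0.351 with an estimated correlation), among them the antiproliferative genes Btg1 (-0.62) and Btg2 (-0.45). Migration receptor genes fell as a list, with 1 up and 5 down of 24 (1 and 7 adjusted over the list alone; camera adjusted p = 0.00221, adjusted p = 0.351 with an estimated correlation). Antigen presentation genes fell as a list, with 1 up and 4 down of 18 (1 and 7 adjusted over the list alone; camera adjusted p = 0.00194, adjusted p = 0.45 with an estimated correlation). Cholesterol biosynthesis genes fell as a list, with 0 up and 2 down of 24 (0 and 0 adjusted over the list alone; camera adjusted p = 0.000711, adjusted p = 0.409 with an estimated correlation). Memory genes fell as a list, with 1 up and 4 down of 26 (1 and 5 adjusted over the list alone; camera adjusted p = 0.030, adjusted p = 0.45 with an estimated correlation). The adjusted p of the memory list was 0.0541 after quantile normalization and 0.131 with fry. With fry it was 0.0897 for the cholesterol list and 0.0973 for antigen presentation. Naive and marginal zone B cell markers fell as a list, with 0 up and 3 down of 7 (0 and 3 adjusted over the list alone; camera adjusted p = 0.0182, adjusted p = 0.351 with an estimated correlation).

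Altogether 1760 of 11266 genes differed between Fraction 2 and Fraction 3, 1033 higher and 727 lower in Fraction 2, and 97 by over 2-fold. For 5421 genes the groups had no overlap, where chance gives 20%. Quantile normalization split the changed genes into 866 higher and 1041 lower. The count was 710 without Fraction 2 library 1, 660 without Fraction 2 library 2, 950 without Fraction 3 library 3 and 1108 in a fit to these groups alone.

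**Figure D2:**
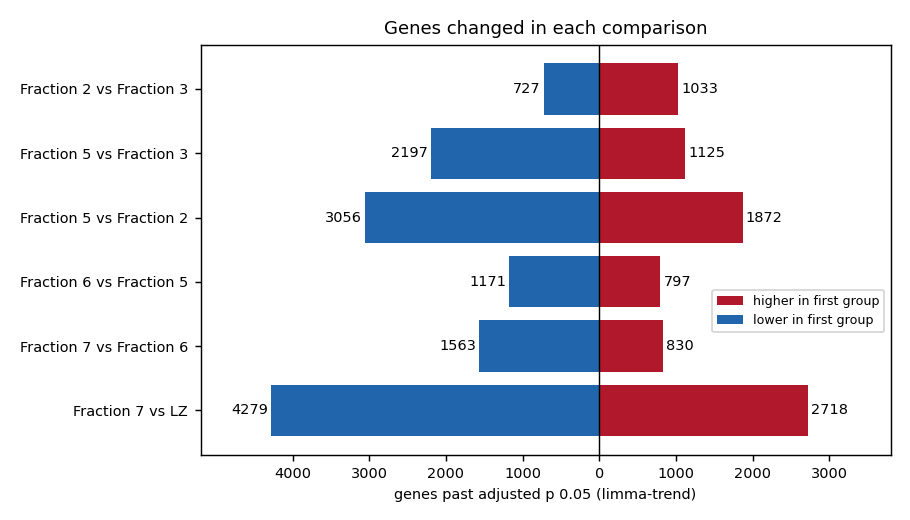
Number of genes past an adjusted p of 0.05 (limma) in each of the 6 comparisons, with genes higher in the first group to the right of 0 and genes lower in it to the left. The counts run from 1760 for Fraction 2 against Fraction 3 to 6997 for Fraction 7 against LZ.

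Fraction 5 was set against Fraction 3 to see how the cells called pro-memory, still high for Bcl6-YFP, differ from light zone cells under selection. The sterol enzyme gene Sqle (9.9 ± 1.59 against 32.9 ± 2.06 FPKM, adjusted p = 4.90e-07) and Slc7a5 (8.51 ± 1.26 against 20.8 ± 3.18 FPKM) fell, as did the transferrin receptor gene Tfrc (7.32 ± 0.824 against 14.9 ± 1.05 FPKM). Ccr6, a chemokine receptor gene of memory B cells, rose (24.4 ± 4.07 against 8.06 ± 1.25 FPKM, log2 change 1.48 ± 0.13 SE, adjusted p = 7.00e-06). The oxysterol receptor gene Gpr183 (14.6 ± 0.755 against 4.58 ± 0.895 FPKM) and Klf2, a transcription factor gene of resting lymphocytes (35.3 ± 5.65 against 16.7 ± 2.67 FPKM), rose too. Bcl6 itself stood at 189 ± 5.61 against 187 ± 16.1 FPKM (adjusted p = 0.889).

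Apart from the gate marker Cd38, the largest rises included Abcg1 (2.03), Ephx1 (1.94), Clec2i (1.89), Fcgrt (1.75), Tnfrsf18 (1.67) and Serpinb1a (1.49), of which Abcg1 encodes a cholesterol exporter. The largest falls included Idi1 (-1.86), Fads2 (-1.76), Fdps (-1.62) and Gins1 (-1.54). Cxcr3 (0.85), Pdcd1lg2 (0.64) and Nr4a1 (0.90) rose, and Myc fell (15.8 ± 2.5 against 24.4 ± 2.97 FPKM).

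Sterol and growth lists fell. Cholesterol biosynthesis genes fell as a list, with 0 up and 21 down of 24 (0 and 22 adjusted over the list alone; camera adjusted p = 1.06e-14, adjusted p = 0.0644 with an estimated correlation). Cyp51 (-1.53) and Insig1 (-1.51) fell. S phase genes fell as a list, with 0 up and 36 down of 38 (0 and 36 adjusted over the list alone; camera adjusted p = 1.67e-22, adjusted p = 0.0528 with an estimated correlation). Mcm2 (-1.24) and Pcna (-1.19) were among them. Genes associated with mTORC1 fell as a list, with 0 up and 29 down of 32 (0 and 29 adjusted over the list alone; camera adjusted p = 5.62e-17, adjusted p = 0.0528 with an estimated correlation), with Shmt2 (-1.43) and Phgdh (-1.14). Ribosome biogenesis genes fell as a list, with 0 up and 29 down of 30 (0 and 29 adjusted over the list alone; camera adjusted p = 3.04e-15, adjusted p = 0.0654 with an estimated correlation), Nop58 (-1.05) among them. Proteasome subunit genes fell as a list, with 0 up and 27 down of 28 (0 and 28 adjusted over the list alone; camera adjusted p = 1.33e-13, adjusted p = 0.0871 with an estimated correlation). Oxidative phosphorylation genes fell as a list, with 0 up and 41 down of 54 (0 and 45 adjusted over the list alone; camera adjusted p = 1.87e-13, adjusted p = 0.0871 with an estimated correlation). Glycolysis genes fell as a list, with 0 up and 12 down of 19 (1 and 13 adjusted over the list alone; camera adjusted p = 1.68e-06, adjusted p = 0.115 with an estimated correlation). Mitosis genes fell as a list, with 0 up and 26 down of 34 (0 and 30 adjusted over the list alone; camera adjusted p = 1.50e-08, adjusted p = 0.284 with an estimated correlation). Psmc3 (-0.58), Atp5g3 (-0.65), Gapdh (-0.64) and Aurkb (-0.76) are examples. Dark zone and hypermutation genes fell as a list, with 0 up and 8 down of 14 (2 and 8 adjusted over the list alone; camera adjusted p = 0.00708, adjusted p = 0.361 with an estimated correlation). The DNA repair genes Lig1 (-1.24) and Ung (-1.21) led this list, whose adjusted p was 0.0681 after quantile normalization.

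Memory and antigen presentation lists were among those that rose. Memory genes rose as a list, with 15 up and 1 down of 26 (17 and 1 adjusted over the list alone; camera adjusted p = 1.12e-08, adjusted p = 0.0528 with an estimated correlation). Zfp318 (1.40) and Cd55 (1.30) rose. Quiescence and egress genes rose as a list, with 15 up and 0 down of 22 (16 and 0 adjusted over the list alone; camera adjusted p = 5.04e-10, adjusted p = 0.0654 with an estimated correlation), with Foxp1 (1.06) and the cell cycle inhibitor gene Cdkn1b (1.00). Migration receptor genes rose as a list, with 13 up and 1 down of 24 (16 and 1 adjusted over the list alone; camera adjusted p = 2.30e-06, adjusted p = 0.0654 with an estimated correlation), the integrin chain gene Itgb7 (1.24) among them. Antigen presentation genes rose as a list, with 9 up and 0 down of 18 (13 and 0 adjusted over the list alone; camera adjusted p = 9.66e-08, adjusted p = 0.167 with an estimated correlation). H2-Oa (0.78) and Ciita (0.34) rose. BCR pathway genes rose as a list, with 9 up and 0 down of 31 (11 and 0 adjusted over the list alone; camera adjusted p = 3.68e-05, adjusted p = 0.272 with an estimated correlation), with Cd72 (1.41) and Cd22 (0.41). Light zone genes rose as a list, with 13 up and 1 down of 22 (14 and 1 adjusted over the list alone; camera adjusted p = 1.63e-07, adjusted p = 0.0528 with an estimated correlation). Survival genes rose as a list, with 8 up and 2 down of 16 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00238, adjusted p = 0.185 with an estimated correlation). Interferon-stimulated genes rose as a list, with 2 up and 0 down of 26 (2 and 0 adjusted over the list alone; camera adjusted p = 0.00911, adjusted p = 0.412 with an estimated correlation). Cytosolic ribosomal protein genes rose as a list, with 4 up and 1 down of 55 (0 and 1 adjusted over the list alone; camera adjusted p = 0.00103, adjusted p = 0.548 with an estimated correlation). After quantile normalization the adjusted p was 0.0831 for the interferon list and 0.118 for ribosomal proteins, and with fry 0.0993 and 0.233. With the LZ gate as reference 4 list calls were lost. The camera adjusted p was then 0.218 for light zone genes, 0.911 for survival genes, 0.422 for ribosomal proteins and 0.166 for dark zone genes. Light zone genes had a mean list score, relative to LZ, of 0.03 ± 0.04 in Fraction 5 and -0.34 ± 0.05 in Fraction 3, and survival genes of -0.03 ± 0.08 and -0.26 ± 0.08, so Fraction 5 lay near LZ and Fraction 3 below it.

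In all, 3322 genes differed between Fraction 5 and Fraction 3, 1125 higher and 2197 lower, 172 of them by over 2-fold. For 4970 genes the groups had no overlap, where chance gives 10%. The split was 1675 higher to 1664 lower after quantile normalization and 1634 to 1879 after median-ratio scaling. Against the whole LZ gate in place of Fraction 3, log2 changes were 0.93 for Ccr6, 0.78 for Gpr183, 0.57 for Klf2, 0.81 for Serpinb1a and -1.11 for Myc. Ccnd2 (1.203) rose against Fraction 3 but was -0.52 against LZ. Bcl2 (0.88) and S1pr1 (0.93) also rose against Fraction 3 but did not pass against LZ (0.43, adjusted p = 0.128, and 0.23, adjusted p = 0.34).

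The same pro-memory cells were compared with Fraction 2, the cells called prone to recycling, to contrast the fates named by the labels among Bcl6-YFP-high cells. The polyamine enzyme gene Srm fell (11 ± 1.27 against 77.3 ± 12.2 FPKM, log2 change -2.70 ± 0.19 SE, adjusted p = 3.98e-07), and so did Myc (15.8 ± 2.5 against 50.003 ± 6.56 FPKM). Ppa1 (-2.64), Smyd2 (-2.59), Shmt1 (-2.43) and Mif (-2.20) were further large falls. Batf (-1.22), Irf4 (-0.70), Ccnd2 (-0.77), Slc7a5 (-2.06) and Tfrc (-1.64) fell as well. Among genes higher in Fraction 5 were those for lipid transport and efflux, Apoe (674 ± 54.3 against 182 ± 19.1 FPKM) and Abca1 (18.2 ± 1.69 against 4.24 ± 0.55 FPKM). Klf2 (35.3 ± 5.65 against 9.02 ± 1.08 FPKM) and Itgb7 (1.77), Cd55 (1.87), Ephx1 (2.04) and Fcgrt (1.88) rose with them. Bach2 (0.94) and Hhex (1.61) rose too.

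All ribosome biogenesis and mitosis genes were lower in Fraction 5. Ribosome biogenesis genes fell as a list, with 0 up and 30 down of 30 (0 and 30 adjusted over the list alone; camera adjusted p = 3.53e-18, adjusted p = 0.0782 with an estimated correlation). Gnl3 (-2.17) and Nolc1 (-1.98) fell. Mitosis genes fell as a list, with 0 up and 34 down of 34 (0 and 34 adjusted over the list alone; camera adjusted p = 5.53e-10, adjusted p = 0.263 with an estimated correlation). Genes associated with mTORC1 fell as a list, with 0 up and 29 down of 32 (0 and 29 adjusted over the list alone; camera adjusted p = 6.13e-15, adjusted p = 0.0782 with an estimated correlation). Phgdh (-1.89) and Hspd1 (-2.09) were among these. S phase genes fell as a list, with 1 up and 36 down of 38 (1 and 37 adjusted over the list alone; camera adjusted p = 6.99e-16, adjusted p = 0.086 with an estimated correlation). Proteasome subunit genes fell as a list, with 0 up and 27 down of 28 (0 and 27 adjusted over the list alone; camera adjusted p = 1.76e-12, adjusted p = 0.118 with an estimated correlation). Oxidative phosphorylation genes fell as a list, with 0 up and 44 down of 54 (1 and 48 adjusted over the list alone; camera adjusted p = 1.44e-11, adjusted p = 0.13 with an estimated correlation). Cholesterol biosynthesis genes fell as a list, with 1 up and 18 down of 24 (1 and 21 adjusted over the list alone; camera adjusted p = 8.27e-07, adjusted p = 0.176 with an estimated correlation). Glycolysis genes fell as a list, with 0 up and 12 down of 19 (0 and 12 adjusted over the list alone; camera adjusted p = 3.82e-05, adjusted p = 0.176 with an estimated correlation). Aurkb (-1.13), Mcm3 (-1.53), Psmd1 (-1.30), Atp5g1 (-1.32), Sqle (-1.38) and Ldha (-1.45) are examples.

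BCR pathway, quiescence and memory lists were among those that rose. BCR pathway genes rose as a list, with 25 up and 0 down of 31 (28 and 0 adjusted over the list alone; camera adjusted p = 3.76e-12, adjusted p = 0.103 with an estimated correlation). Cd79b (0.97), Dok3 (1.05) and Cd72 (1.59) rose. Quiescence and egress genes rose as a list, with 20 up and 0 down of 22 (20 and 1 adjusted over the list alone; camera adjusted p = 5.47e-10, adjusted p = 0.088 with an estimated correlation). Memory genes rose as a list, with 18 up and 1 down of 26 (19 and 1 adjusted over the list alone; camera adjusted p = 1.01e-07, adjusted p = 0.0782 with an estimated correlation). Migration receptor genes rose as a list, with 18 up and 0 down of 24 (18 and 0 adjusted over the list alone; camera adjusted p = 1.83e-07, adjusted p = 0.0782 with an estimated correlation). Foxp1 (1.58), Btg2 (1.14), Ccr6 (1.29) and S1pr4 (1.47) were among these rises. Antigen presentation genes rose as a list, with 14 up and 1 down of 18 (14 and 1 adjusted over the list alone; camera adjusted p = 6.42e-07, adjusted p = 0.191 with an estimated correlation). Interferon-stimulated genes rose as a list, with 8 up and 1 down of 26 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00542, adjusted p = 0.451 with an estimated correlation). GC identity genes rose as a list, with 9 up and 3 down of 21 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0249, adjusted p = 0.546 with an estimated correlation). H2-Ob (0.91), Ddx58 (1.61) and Pax5 (0.68) are examples. The GC identity list holds Efnb1, for which Fraction 5 was sorted high, so the sort may have set part of that list's rise. Efnb1 was 57.9 to 67.5 FPKM in the Fraction 5 libraries and 35.6 and 33.5 in those of Fraction 2. Naive and marginal zone B cell markers rose as a list, with 5 up and 0 down of 7 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00672, adjusted p = 0.13 with an estimated correlation).

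Between Fraction 5 and Fraction 2, 4928 genes differed, 1872 higher and 3056 lower, 833 by over 2-fold. For 7038 genes the groups had no overlap, where chance gives 20%. The split was 2713 to 2479 after quantile normalization and 2534 to 2657 after median-ratio scaling.

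**Figure D3:**
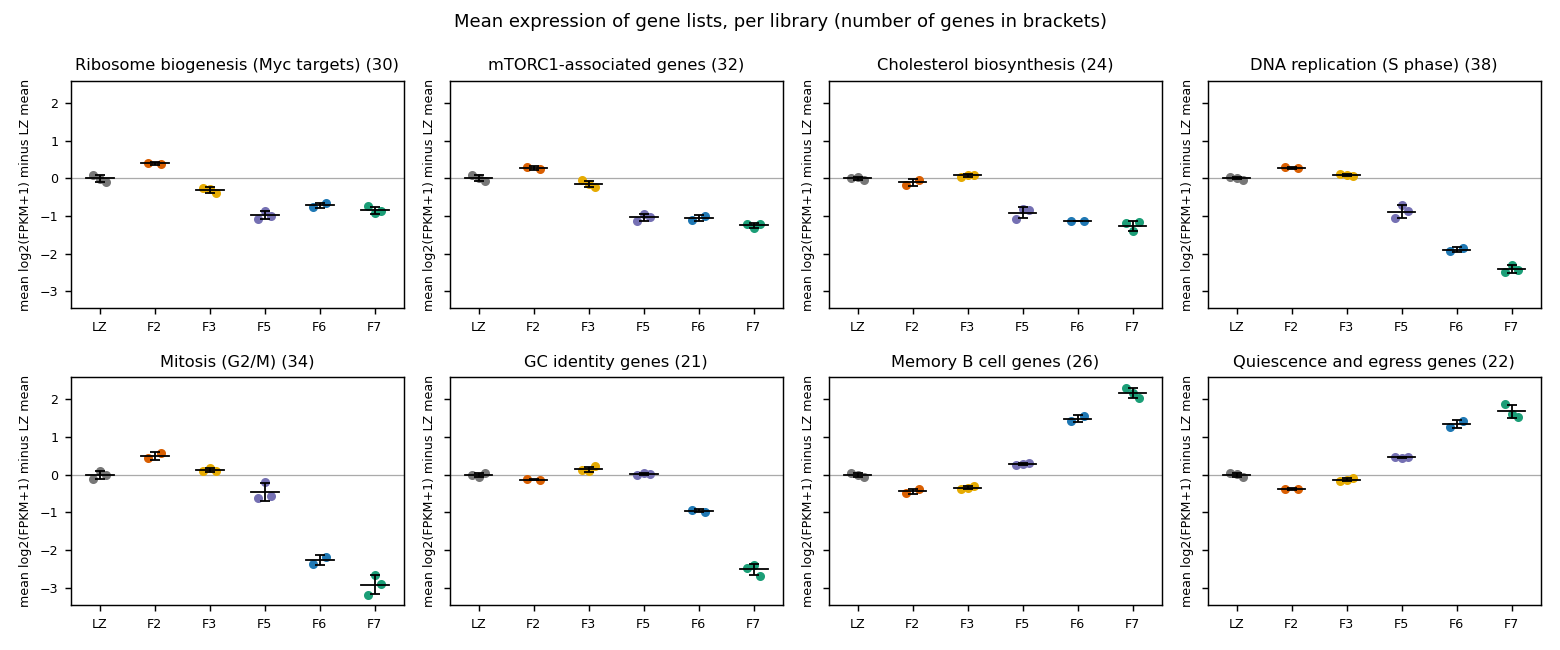
Mean log2(FPKM + 1) of the tested genes of 8 lists in each library, minus the mean of the LZ libraries, with 1 point per library, a bar at the group mean and whiskers of 1 SD. The mTORC1 list lay at 0.27 in Fraction 2, -1.03 in Fraction 5 and -1.05 in Fraction 6, while the mitosis list lay at 0.50, -0.45 and -2.27.

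Fraction 6 against Fraction 5 contrasts the cells called pre-memory, low for Bcl6-YFP, with the pro-memory cells, both high for Efnb1. The egress receptor gene S1pr1 rose (37.3 ± 6.82 against 4.17 ± 1.11 FPKM, log2 change 2.90 ± 0.19 SE, adjusted p = 4.44e-07). Ccr6 (97.8 ± 2.24 against 24.4 ± 4.07 FPKM) rose too. Klf2 (174 ± 19.1 against 35.3 ± 5.65 FPKM), the survival gene Bcl2 (8.22 ± 0.176 against 2.65 ± 0.166 FPKM) and Klf3 (2.46), Hhex (1.40) and Zbtb32 (1.70) rose with them. The GC gene Gcet2, now called Gcsam, fell (4.67 ± 0.36 against 36.6 ± 5.5 FPKM, adjusted p = 9.95e-09). So did the confinement receptor gene S1pr2 (35.2 ± 0.601 against 152 ± 2.78 FPKM) and Mki67, a marker of cycling cells (17.6 ± 1.54 against 76.6 ± 17.4 FPKM).

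Further rises were Pml (2.84), Ccl22 (2.82), Arhgef18 (2.47), Gpr183 (1.33) and Irf4 (1.04). Large falls were H1fx (-2.85), Cdkn3 (-2.67), Cdc20 (-2.48), Stmn1 (-2.43), Ccrl1 (-2.43) and Birc5 (-2.42). Ccnd3 (-1.38) and Bach2 (-0.72) fell as well. S100a10 (3.31) and Plac8 (2.47) rose with a wide spread between the Fraction 6 libraries. Without Fraction 6 library 2, S100a10 was 2.65 (adjusted p = 0.0537) and Plac8 1.63.

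Cell cycle and GC lists fell while memory lists rose. The GC identity list holds Bcl6, whose reporter parted these gates, so part of its fall was set by the sort. Mitosis genes fell as a list, with 0 up and 34 down of 34 (0 and 34 adjusted over the list alone; camera adjusted p = 3.94e-38, adjusted p = 0.0521 with an estimated correlation). Plk1 (-2.34) and Kif20a (-2.16) fell. S phase genes fell as a list, with 0 up and 33 down of 38 (0 and 35 adjusted over the list alone; camera adjusted p = 1.94e-28, still adjusted p = 0.0399 with an estimated correlation), with Rrm2 (-2.25) and Mcm7 (-1.31). GC identity genes fell as a list, with 0 up and 18 down of 21 (0 and 18 adjusted over the list alone; camera adjusted p = 1.67e-17, still adjusted p = 0.0408 with an estimated correlation), with Gm600 (-1.32) and Pou2af1 (-0.94). Memory genes rose as a list, with 20 up and 1 down of 26 (20 and 1 adjusted over the list alone; camera adjusted p = 9.34e-15, still adjusted p = 0.0321 with an estimated correlation). Dark zone and hypermutation genes fell as a list, with 0 up and 10 down of 14 (0 and 12 adjusted over the list alone; camera adjusted p = 4.33e-11, adjusted p = 0.0645 with an estimated correlation), with Lig1 (-1.75). Quiescence and egress genes rose as a list, with 15 up and 0 down of 22 (15 and 0 adjusted over the list alone; camera adjusted p = 2.10e-10, adjusted p = 0.0777 with an estimated correlation). The mTORC1-associated list did not pass (camera adjusted p = 0.848).

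Further lists went both ways. Ribosome biogenesis genes rose as a list, with 10 up and 0 down of 30 (13 and 0 adjusted over the list alone; camera adjusted p = 1.21e-05, adjusted p = 0.338 with an estimated correlation), Polr1b (0.68) among them. Proteasome subunit genes fell as a list, with 0 up and 13 down of 28 (0 and 16 adjusted over the list alone; camera adjusted p = 1.14e-07, adjusted p = 0.266 with an estimated correlation). Oxidative phosphorylation genes fell as a list, with 0 up and 16 down of 54 (0 and 17 adjusted over the list alone; camera adjusted p = 1.14e-07, adjusted p = 0.266 with an estimated correlation). Cholesterol biosynthesis genes fell as a list, with 0 up and 6 down of 24 (1 and 8 adjusted over the list alone; camera adjusted p = 0.00726, adjusted p = 0.444 with an estimated correlation). Psmd14 (-0.56), Atp5a1 (-0.40) and Acat2 (-0.62) fell. Survival genes rose as a list, with 5 up and 1 down of 16 (6 and 1 adjusted over the list alone; camera adjusted p = 0.000186, adjusted p = 0.158 with an estimated correlation). Light zone genes rose as a list, with 8 up and 2 down of 22 (8 and 3 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.198 with an estimated correlation). Early activation genes rose as a list, with 7 up and 2 down of 19 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.374 with an estimated correlation). Interferon-stimulated genes rose as a list, with 5 up and 0 down of 26 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00386, adjusted p = 0.421 with an estimated correlation). Ccr7 (1.96), Nfkbid (0.74) and Ddx58 (1.27) rose. Migration receptor genes rose as a list, with 11 up and 6 down of 24 (11 and 7 adjusted over the list alone; camera adjusted p = 0.0219, adjusted p = 0.374 with an estimated correlation), so its members went both ways. Antigen presentation genes rose as a list, with 3 up and 0 down of 18 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0393, adjusted p = 0.601 with an estimated correlation). With fry the adjusted p of this last list was 0.179.

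Macrophage and neutrophil markers rose as a list, with 4 up and 0 down of 12 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0393, adjusted p = 0.421 with an estimated correlation). With fry the adjusted p of these markers was 0.0866. Itgam (0.93) and Emr1 (0.90) rose, the latter now called Adgre1, but without Fraction 6 library 2 neither passed (0.62, adjusted p = 0.119, and 0.79, adjusted p = 0.0557). In this comparison 1968 genes differed, 797 higher and 1171 lower, 398 by over 2-fold. For 5401 genes the groups had no overlap, where chance gives 20%. The count was 1152 without Fraction 6 library 1 and 1170 without library 2.

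Fraction 7 against Fraction 6 contrasts the cells called mature memory, low for Efnb1, with the pre-memory cells. The GC gene S1pr2 fell (4.27 ± 0.749 against 35.2 ± 0.601 FPKM, log2 change -2.79 ± 0.11 SE, adjusted p = 1.55e-09). Mef2b (-3.12), Mybl1 (-3.07) and Bach2 (-1.39) fell with it. The scaffold protein gene Ahnak (55.9 ± 15.9 against 2.34 ± 0.748 FPKM, adjusted p = 5.97e-08) and the transcription factor gene Bhlhe41 (71.3 ± 9.3 against 4.86 ± 1.73 FPKM) rose. Zbtb32 (45.1 ± 11.1 against 5.69 ± 2.53 FPKM), the chemokine receptor gene Cxcr3 (35.3 ± 4.61 against 5.0 ± 1.15 FPKM) and S1pr1 (1.47) and Bcl2 (1.09) rose as well. Klf2 stood at 236 ± 44.5 against 174 ± 19.1 FPKM (adjusted p = 0.126, and 0.023 after quantile normalization).

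Other large rises were S100a6 (4.16), Ly6c2 (3.95), Plac8 (3.92), Sspn (3.74), Pdlim1 (3.36) and S100a10 (3.34). Other large falls were Basp1 (-2.65), Rassf6 (-2.38) and Crisp3 (-2.34). Rpl26 fell (-3.81), though its reads may be shared with near-identical copies. Ski (1.93), Cd80 (1.26) and Tle3 (0.99) rose. Ccnd3 (-1.30), Nt5e (-1.04), Egr1 (-1.03) and Tnfrsf13c (-0.93) fell, the last of which encodes the BAFF receptor.

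GC, cell cycle and BCR pathway lists were among those that fell. The GC identity list holds Efnb1, the marker that parted these gates, so part of its fall was set by the sort. GC identity genes fell as a list, with 0 up and 21 down of 21 (0 and 21 adjusted over the list alone; camera adjusted p = 6.46e-23, still adjusted p = 0.0472 with an estimated correlation), led by Gm600 (-2.91). Dark zone and hypermutation genes fell as a list, with 0 up and 11 down of 14 (0 and 13 adjusted over the list alone; camera adjusted p = 8.70e-09, adjusted p = 0.154 with an estimated correlation). S phase genes fell as a list, with 0 up and 25 down of 38 (0 and 29 adjusted over the list alone; camera adjusted p = 3.52e-09, adjusted p = 0.241 with an estimated correlation). Mitosis genes fell as a list, with 0 up and 23 down of 34 (0 and 30 adjusted over the list alone; camera adjusted p = 8.70e-09, adjusted p = 0.417 with an estimated correlation). Rgs13 (-2.25), E2f2 (-0.84) and Tacc3 (-0.98) fell. Light zone genes fell as a list, with 1 up and 12 down of 22 (1 and 13 adjusted over the list alone; camera adjusted p = 2.60e-05, adjusted p = 0.154 with an estimated correlation), with Cd83 (-1.51) and Marcksl1 (-1.73). BCR pathway genes fell as a list, with 1 up and 19 down of 31 (2 and 20 adjusted over the list alone; camera adjusted p = 1.20e-05, adjusted p = 0.364 with an estimated correlation). Antigen presentation genes fell as a list, with 2 up and 9 down of 18 (2 and 11 adjusted over the list alone; camera adjusted p = 0.00024, adjusted p = 0.454 with an estimated correlation). Pro-apoptotic genes fell as a list, with 1 up and 8 down of 19 (1 and 9 adjusted over the list alone; camera adjusted p = 0.00532, adjusted p = 0.241 with an estimated correlation). Fyn (-0.98), Ciita (-0.74) and Fas (-1.39) are examples, Fas being a death receptor gene.

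Memory and related lists rose. Memory genes rose as a list, with 13 up and 4 down of 26 (17 and 6 adjusted over the list alone; camera adjusted p = 8.37e-06, adjusted p = 0.154 with an estimated correlation). Il6ra (1.66) and Pml (2.66) rose. Quiescence and egress genes rose as a list, with 8 up and 3 down of 22 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.511 with an estimated correlation), with Rb1 (1.03), and the adjusted p with fry was 0.0675. Interferon-stimulated genes rose as a list, with 8 up and 0 down of 26 (10 and 0 adjusted over the list alone; camera adjusted p = 8.37e-06, adjusted p = 0.281 with an estimated correlation), with Bst2 (1.35). Plasma cell genes rose as a list, with 8 up and 1 down of 21 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00024, adjusted p = 0.281 with an estimated correlation). Fkbp11 (2.46) and Tnfrsf17 (1.98) were among the rises. With Fraction 7 libraries 2 and 3 left out, which leaves library 1 alone with a spread taken from the other groups, 3 plasma cell genes rose and 1 fell and the list did not pass (camera adjusted p = 0.286).

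Between Fraction 7 and Fraction 6, 2393 genes differed, 830 higher and 1563 lower, 435 by over 2-fold. For 5222 genes the groups had no overlap, where chance gives 20%. The split was 1205 to 1470 after quantile normalization and 1226 to 1275 after median-ratio scaling. The count was 1561 without Fraction 6 library 1, 1334 without Fraction 6 library 2, 1589 with Fraction 7 library 1 alone, and 1248 in a fit to these groups alone.

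**Figure D4:**
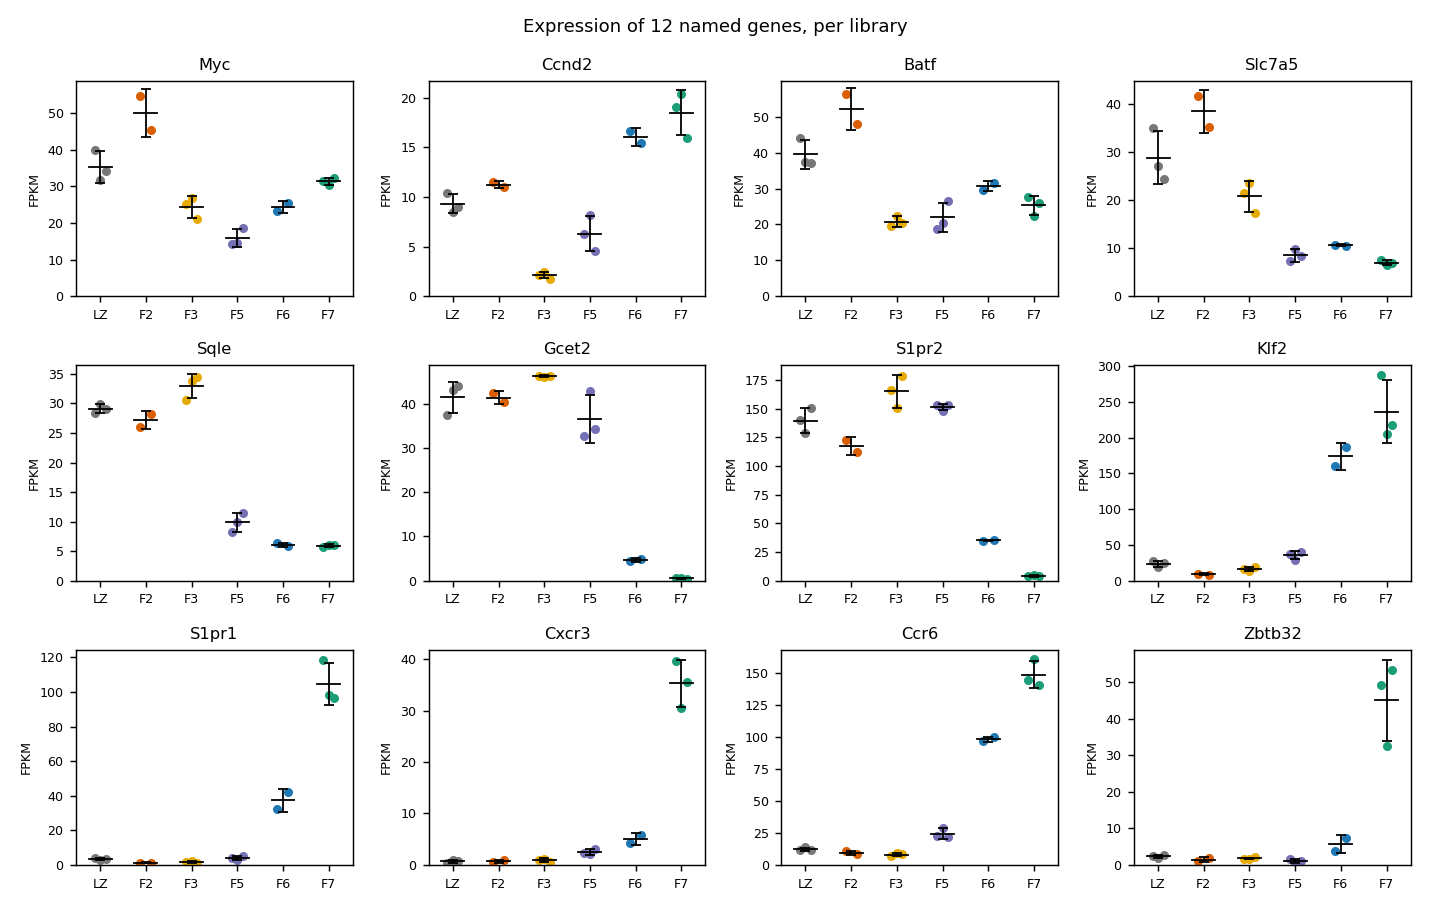
FPKM of 12 genes in LZ and Fractions 2, 3, 5, 6 and 7 (F2 to F7), with 1 point per library, a bar at the group mean and whiskers of 1 SD. Mean Myc was 50.003 FPKM in Fraction 2 and 15.8 in Fraction 5, while mean S1pr1 was 4.17 in Fraction 5, 37.3 in Fraction 6 and 104 in Fraction 7. Myc was higher than in Fraction 5 in the libraries of Fraction 6 (23.2 and 25.5 FPKM) and Fraction 7 (30.3 to 32.1 FPKM).

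Fraction 7 against the whole LZ gate contrasts the cells called mature memory with all light zone cells sorted. All gates were sorted on day 10, so whether cells pass from gate to gate was not tested. Memory cells carried more S1pr1 (104 ± 12.3 against 3.36 ± 0.543 FPKM, log2 change 4.60 ± 0.17 SE, adjusted p = 1.29e-10). Ccr6 (148 ± 10.5 against 12.3 ± 1.14 FPKM) and Klf2 (236 ± 44.5 against 23.4 ± 4.1 FPKM) rose too. The GC genes Gcet2 (0.518 ± 0.169 against 41.5 ± 3.49 FPKM) and S1pr2 (4.27 ± 0.749 against 139.7 ± 10.8 FPKM, adjusted p = 9.17e-13) fell, as did the cycling marker Mki67 (11.1 ± 3.27 against 107 ± 12.1 FPKM). The largest rises included Plac8 (7.20), S100a10 (5.82), Ahnak (5.42), S100a6 (5.36), Pml (5.12), Bhlhe41 (5.12) and Ly6c2 (4.99). Further falls were Basp1 (-4.71), Mef2b (-4.62), H1fx (-4.50) and Stmn1 (-4.35). Cxcr3 (4.42), Zbtb32 (3.76), Ski (3.13), Bcl2 (2.86), Gpr183 (2.47) and Hhex (2.44) rose, and Ccnd3 (-2.74) and Slc7a5 (-1.88) fell.

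GC, cell cycle and biosynthesis lists fell. GC identity genes fell as a list, with 0 up and 21 down of 21 (0 and 21 adjusted over the list alone; camera adjusted p = 2.26e-11, adjusted p = 0.114 with an estimated correlation), led by Gm600 (-4.21). Dark zone and hypermutation genes fell as a list, with 0 up and 14 down of 14 (0 and 14 adjusted over the list alone; camera adjusted p = 1.16e-07, adjusted p = 0.15 with an estimated correlation). Mitosis genes fell as a list, with 0 up and 34 down of 34 (0 and 34 adjusted over the list alone; camera adjusted p = 2.69e-16, adjusted p = 0.164 with an estimated correlation). Proteasome subunit genes fell as a list, with 0 up and 28 down of 28 (0 and 28 adjusted over the list alone; camera adjusted p = 7.23e-10, adjusted p = 0.164 with an estimated correlation). S phase genes fell as a list, with 0 up and 37 down of 38 (0 and 37 adjusted over the list alone; camera adjusted p = 2.33e-17, adjusted p = 0.114 with an estimated correlation). Lig1 (-3.38), Kif20a (-2.95), Psmb7 (-1.37) and Uhrf1 (-3.65) are examples. Genes associated with mTORC1 fell as a list, with 1 up and 30 down of 32 (1 and 30 adjusted over the list alone; camera adjusted p = 1.37e-08, adjusted p = 0.15 with an estimated correlation), with Psat1 (-2.90) and Mthfd2 (-2.26). Cholesterol biosynthesis genes fell as a list, with 0 up and 23 down of 24 (0 and 23 adjusted over the list alone; camera adjusted p = 1.16e-07, adjusted p = 0.164 with an estimated correlation). Oxidative phosphorylation genes fell as a list, with 0 up and 52 down of 54 (0 and 52 adjusted over the list alone; camera adjusted p = 2.56e-11, adjusted p = 0.164 with an estimated correlation). Ribosome biogenesis genes fell as a list, with 0 up and 28 down of 30 (0 and 29 adjusted over the list alone; camera adjusted p = 2.53e-07, adjusted p = 0.192 with an estimated correlation). Glycolysis genes fell as a list, with 3 up and 14 down of 19 (3 and 14 adjusted over the list alone; camera adjusted p = 0.00942, adjusted p = 0.396 with an estimated correlation). Idi1 (-2.53), Atp5g3 (-1.46), Rrs1 (-1.51) and Pfkp (-1.61) fell. Pro-apoptotic genes fell as a list, with 1 up and 14 down of 19 (2 and 14 adjusted over the list alone; camera adjusted p = 0.0177, adjusted p = 0.192 with an estimated correlation), with Fas (-1.79).

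Memory, quiescence and interferon lists rose. Memory genes rose as a list, with 21 up and 3 down of 26 (21 and 3 adjusted over the list alone; camera adjusted p = 7.55e-10, adjusted p = 0.114 with an estimated correlation), with Cd55 (4.09). Quiescence and egress genes rose as a list, with 18 up and 0 down of 22 (18 and 0 adjusted over the list alone; camera adjusted p = 2.12e-10, adjusted p = 0.114 with an estimated correlation), with Klf3 (3.58). Interferon-stimulated genes rose as a list, with 17 up and 0 down of 26 (18 and 0 adjusted over the list alone; camera adjusted p = 1.53e-06, adjusted p = 0.176 with an estimated correlation), with Ddx58 (3.02) and Mx1 (1.98). Migration receptor genes rose as a list, with 12 up and 11 down of 24 (13 and 11 adjusted over the list alone; camera adjusted p = 0.0397, adjusted p = 0.396 with an estimated correlation), so its members went both ways. Itgb7 (3.14) and Itga4 (3.01) rose, and the list's adjusted p was 0.0862 after median-ratio scaling and 0.053 with Fraction 7 library 1 alone. Macrophage and neutrophil markers rose as a list, with 4 up and 0 down of 12 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0427, adjusted p = 0.405 with an estimated correlation). Itgam (3.30), Tyrobp (2.49) and Mpeg1 (1.74) rose, and that list's adjusted p was 0.237 with library 1 alone. Naive and marginal zone B cell markers, 4 up and 2 down of 7, did not pass with camera (adjusted p = 0.192) but did with fry (0.000402).

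In total 6997 genes differed between Fraction 7 and LZ, 2718 higher and 4279 lower, 1970 by over 2-fold. For 7256 genes the groups had no overlap, where chance gives 10%. The median log2 change over all tested genes was -0.10, and the split was 3464 to 3467 after quantile normalization and 3829 to 3468 after median-ratio scaling. After quantile normalization 5903 of the 6997 genes were called again, and 184 of the 6997 changed sign.

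Lists that did not pass in a comparison had camera adjusted p-values of 0.0668 to 0.964 for Fraction 2 against Fraction 3, 0.0557 to 0.702 and 0.111 to 0.93 for Fraction 5 against Fractions 3 and 2, 0.137 to 0.965 for Fraction 6 against Fraction 5, 0.0529 to 0.728 for Fraction 7 against Fraction 6 and 0.192 to 0.931 for Fraction 7 against LZ. Of 156 list results 97 passed, and in these the median, the mean and the test had 1 sign; in 17 of the others they differed in sign. T cell and erythroid markers passed in none of the 6 comparisons. Over the groups, means of the most abundant T cell markers were 6.86 to 32 FPKM for Lck, a kinase gene that B cells can also express, and 0.584 to 7.13 FPKM for Lat. In the macrophage list means were 10.4 to 39.9 FPKM for Mpeg1, highest in Fraction 7, and 6.97 to 12 FPKM for Cd68. Of erythroid markers, Beta-s, now called Hbb-bs, was 47.6 ± 21.8 FPKM in LZ, and group means of Hbb-b2 were 6.03 to 33.9 FPKM. Too few tested genes were left for the dendritic cell (4 genes), natural killer cell (1), platelet (0) and stroma (1) lists, which were not tested. Their most abundant members, with the range of group means, were Flt3 (13.6 to 29.1 FPKM) and Xcr1 (0.836 to 1.21 FPKM), Prf1 (0.325 to 1.32 FPKM) and Eomes (0.0658 to 0.252 FPKM), Itga2b (0.0402 to 0.437 FPKM) and Gp9 (0 to 0.101 FPKM), and Mfge8 (0.835 to 3.03 FPKM) and Madcam1 (0.0337 to 0.506 FPKM). The naive and marginal zone markers Fcer2a (269 to 553 FPKM) and Dtx1 (32.7 to 54.8 FPKM) are also expressed by other B cells. The mean score of their list of 7 genes, relative to LZ, was 0.18 ± 0.08 in Fraction 5, 0.43 ± 0.01 in Fraction 6 and 0.73 ± 0.03 in Fraction 7. Fcer2a and Dtx1 went against that score in Fraction 7. Mean Fcer2a was 352 FPKM in LZ, 553 in Fraction 6 and 328 in Fraction 7. Mean Dtx1 was 47.4, 46.6 and 32.7 FPKM in the same groups. The list did not pass with camera in Fraction 6 against Fraction 5 (adjusted p = 0.224) or in Fraction 7 against Fraction 6 (adjusted p = 0.722, 3 up and 3 down), and with fry the adjusted p was 0.0779 and 0.715.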

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

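The test without Fraction 7 libraries 2 and 3 was chosen only after the result was seen; the other alternatives were written before the data were examined. Over all genes given by the naming rule, 101 of 545 results past the threshold lost their call when at least 1 library was left out (0 reversed), 47 in a fit to the groups compared alone, 37 without a filter, 15 with LZ as reference for Fraction 5 (5 reversed), 11 with a pseudocount of 0.1, 11 after quantile normalization (1 reversed), 8 with the replicate block, 6 without Fraction 7 libraries 2 and 3, 4 after median-ratio scaling, 3 with array weights, 2 with Fraction 3 as reference for Fraction 7 (1 reversed) and 1 with the stricter filter. Genes named in the report were mostly taken from those that held, so they overstate how stable calls are. Reversed among them were Ccnd2 (-0.52) in Fraction 5 with LZ as reference, and Bcl6, not past the threshold, in Fraction 5 against Fraction 3 without Fraction 3 library 1 (-0.028, in a range of -0.028 to 0.090 over left-out libraries).

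Numbers of changed genes moved over 1.5 times in a fit to the groups compared alone for Fraction 2 against Fraction 3 (1108 in place of 1760) and Fraction 7 against Fraction 6 (1248 in place of 2393), and for the latter without Fraction 7 libraries 2 and 3 (1589). Leaving out each library gave 660 to 1411 for Fraction 2 against Fraction 3, 2355 to 2975 and 3817 to 4698 for Fraction 5 against Fractions 3 and 2, 1152 to 1817 for Fraction 6 against Fraction 5, 1334 to 2491 for Fraction 7 against Fraction 6 and 6489 to 6793 for Fraction 7 against LZ. Moves over 1.5 times came from either Fraction 2 library, Fraction 3 library 3 and either Fraction 6 library; a group of 2, like Fraction 7 without libraries 2 and 3, is then left with 1 library, assumed to vary like the other groups, and beyond that the cause was not tested. Of 93 pathway list calls 4 held with an estimated correlation, 83 with fry, 89 after quantile normalization and 92 after median-ratio scaling, with 0 reversed. With the other reference, 14 of 18 held for Fraction 5 against LZ and 15 of 15 for Fraction 7 against Fraction 3. Count-based tools were not run because the values are FPKM.

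With the replicate number as a block, 1618, 3518, 4908, 2076, 2471 and 7081 genes changed, in the order of the report. The labels do not say that numbers pair samples: the 36 same-number pairs had correlations of -0.18 to 0.16, with 5 over 0.1, and 8 of 16 libraries correlated best with their own number.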

Other observations

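All tests in this part except the 2 counts of other splits of the libraries were chosen only after the result was seen.

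Genes were also grouped into 158 families by the stem of their symbols, a grouping chosen after the values were seen. GTPases of the Gimap family, which act in lymphocyte survival, rose in Fraction 7 against LZ: 8 of 8 tested members, with a median log2 change of 1.38 (camera adjusted p = 2.74e-05, and adjusted p = 0.358 with an estimated correlation). Gimap4 was 472 ± 42.0 against 121 ± 9.46 FPKM and Gimap3 255 ± 21.9 against 68.5 ± 1.66 FPKM. In Fraction 5 against Fraction 3, 6 of 8 rose (median 0.48, adjusted p = 0.000267, and 0.316 with an estimated correlation), and in Fraction 6 against Fraction 5, 7 of 8 (median 0.58, adjusted p = 7.70e-05, and 0.378 with an estimated correlation). By smallest p Gimap ranked 3 of the 32 families that passed in Fraction 7 against LZ and 5 of 41 in Fraction 5 against Fraction 3. It ranked 4 of 17 in Fraction 6 against Fraction 5 and 1 of 4 in Fraction 7 against Fraction 6. In Fraction 5 against Fraction 2 it ranked only 18 of 40. It was not among the 22 that passed in Fraction 2 against Fraction 3. The family was singled out after its values were seen. Members of such families may share reads between paralogs, which was not tested; after quantile normalization the Gimap median in Fraction 7 against LZ was 1.72.

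Splits of the 6 libraries into other groups of 3 number 10 with the real one, too few for a share under 0.05. Every other split also mixes both groups, so a difference between them enters the spread. Few calls in those splits were therefore bound to follow. For Fraction 5 against Fraction 3 the real split gave 3322 genes and the highest other 1, so 1 of 10 reached the real value. For Fraction 7 against LZ the real split gave 6997 and the highest other 1, again 1 of 10.

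Libraries 2 and 3 of Fraction 7 list 16782 and 18234 genes above 0, against 13989 to 15152 in the other 14. Greater depth is argued against: the higher of these libraries had 1.04 times the median depth of the others. An even low background, as from genomic DNA, could account for it. Of 1441 olfactory and vomeronasal receptor genes, taken as silent in lymphocytes, 25.5% and 43.7% were above 0. Elsewhere at most 9.58% were, a ratio of 2.66 for the lower library. These genes are part of the count to be explained, so the test partly restates the pattern. It cannot speak to unspliced RNA, which silent genes do not make. RNA of other spleen cells stays open, with 1 of 90 markers (Tyrobp) above the highest other library by over 2 FPKM in both. No biological explanation was tested.

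In Fraction 7 libraries 1, 2 and 3 some plasma cell genes differed: Igj, now called Jchain, was 46.9, 296 and 292 FPKM, Xbp1 34.0, 84.9 and 81.3, and Sdc1 0.502, 4.44 and 4.51. The hypothesis of plasma cells mixed into libraries 2 and 3 fits 1 test: the other 18 plasma cell genes had a median log2 difference from library 1 of 0.23, at percentile 100 among 10000 random lists of matched expression, with 12 higher in both. That support is weak, as library 1 stands alone and random lists take genes as independent. Genes of the plasma cell list move together, with an estimated correlation of 0.21. Lower in both were Mzb1 (2010001M09Rik; 235, 211 and 211 FPKM), Fkbp11 (13.7, 8.72 and 11.6) and Slamf7 (18.4, 15.6 and 16.7). The CD138-negative gate was set to remove plasma cells, yet Sdc1, which encodes CD138, was itself higher in libraries 2 and 3. A difference in the memory cells themselves, which no test here addressed, stays open.

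Genes associated with mTORC1 were lower in Fraction 5 than in Fraction 3, with a list median of -0.91 (-0.99 to -0.84 over left-out libraries), and mitosis genes by a median of -0.62. In Fraction 6 against Fraction 5 the mitosis median was -1.93 and that of the mTORC1 list -0.0756 (-0.13 to 0.00). The S phase list fell to a similar degree in both comparisons. Its mean score relative to LZ was 0.08 in Fraction 3, -0.88 in Fraction 5 and -1.89 in Fraction 6. The far larger fall in Fraction 6 against Fraction 5 was thus seen for mitosis genes, not for S phase genes. The mTORC1 median there argues against fewer cells in S phase or mitosis as the whole cause only if nothing else moved mTORC1 genes. Yet Myc was 14.2 to 18.7 FPKM in the Fraction 5 libraries and 23.2 and 25.5 in those of Fraction 6. Ribosome biogenesis genes also rose as a list in Fraction 6 against Fraction 5. An opposing rise could hide a fall, so the test cannot decide the question. Both comparisons use the Fraction 5 libraries, and values low there by chance would move these medians apart. A smaller share of cycling cells as all or part of the cause, and a lower mTORC1 activity, which transcripts do not measure, stay open.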
